A study of Mus musculus with 8 samples.

How the data were processed

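Poly(A) RNA from mouse hearts was sequenced 8 weeks after transverse aortic constriction, a surgical narrowing of the aorta that loads the left ventricle with pressure. The labels give 4 wildtype libraries and 4 libraries called Mertk knockdown, all from C57 mice and all operated, so no unoperated heart was analysed here. Per the labels' protocols, RNA was taken up in Trizol, messenger RNA was selected with oligo(dT) beads, the second strand was marked with dUTP and removed, and the libraries were read as paired ends on an Illumina NovaSeq. The labels do not say how Mertk was lowered, in which cells, or whether each replicate was a separate mouse. P-values therefore measure the spread between these libraries, part of which could be technical.

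The deposited table holds 30445 genes with whole-number read counts and FPKM (fragments per kilobase of gene, scaled to the fragment total of the library) for each of the 8 libraries, per the file headers. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used with build mm10. The notes, as used here, give no role or order for these tools, and whether the authors' counts were made with regard to strand is not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical gene copies, may therefore be shared between rows. The annotation release is not stated either. Of the gene identifiers, 30367 were found in GENCODE release M21 for the same build and 78 were not; 30365 of them overlapped their M21 position and 27504 (90.3% of the table) had the same start and end. Coordinates below are those of the deposited table, on mm10 and counted from 1. All per-sample columns matched a library by name, and no row lacked a gene name.

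Total counts ran from 59287621 to 71571173 per library. A gene without counts in the shallowest library could still be present at up to 0.0506 CPM (counts scaled to a common library total), the level of 3 counts there, and such floors cover counting error only. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom over genes with a summed count of at least 20 was between 37.89 and 198.7.

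The deposited counts were used as they are. The main test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust = TRUE, glmQLFTest, two-sided) in R 4.3.3, with TMM normalization, the filterByExpr filter and no covariate, on all 8 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Log2 fold changes are labelled Mertk knockdown minus wildtype, and group levels are mean CPM ± SD with TMM-scaled library sizes. The script was tested on simulated counts with the real means, library sizes and 200 changed genes. Of the changed genes it called 13.4% at 1.5-fold, 55.2% at 2-fold and 71.2% at 4-fold among 17240 simulated genes that passed the filter, with 9 false calls among 102 and 0 of the wrong sign. In a second simulation the interferon-stimulated list, shifted 1.5-fold down, was called (adjusted p 7.345e-24 by camera, described below), and 1 of 35 unshifted lists was called as well. Both simulations drew each gene independently, so they do not test how list calls behave when genes of a list vary together. In the real data the inter-gene correlation of the interferon-stimulated list was estimated at 0.6403.

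Before the data were examined, 38 gene lists (12 of them primary) were fixed for interferon responses, macrophages and other cell types, hypertrophy, matrix, metabolism, stress and foreign tissue. Of their 613 different genes, 578 were tested. Lists with at least 5 tested members (37 lists) were compared with all other tested genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists. Members past the threshold were counted over all genes and also adjusted over the list alone. List scores are the mean log2 CPM of the tested members per library (prior count 2), compared by an exact permutation test, two-sided, in which 4 libraries against 4 can reach no p under 0.02857.

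The rule for named genes was also fixed beforehand. It takes Mertk, Axl, Tyro3, Gas6 and Pros1. It then takes the 10 called genes with the largest log2 fold change in each direction, among those with a mean of at least 1 CPM, no overlap between the groups and no predicted or clone name. From each list it takes up to 4 called members, or in a primary list without any the 2 members with the smallest p, and it adds the readouts Nppa, Nppb, Myh7, Myh6, Col1a1, Col3a1 and Postn. This gave 61 genes, of which 2 are not reported here and were left out of the search for single outlying libraries, while all counts of genes and list tests include them. Other genes in the text were chosen after their values were seen, or illustrate a list.

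The alternatives were RLE and upper quartile factors, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, and limma-trend on the deposited FPKM as log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or no filter. They further included the replicate number as a block, each library left out in turn, 2 other thresholds, and for the lists an estimated correlation and fry. Alternatives chosen after seeing the data used a hepatocyte or an atrial marker score as a covariate, only the 5 libraries with hepatocyte transcripts (1 wildtype and 4 labelled, the lone library being assumed to vary like the others), only the 5 without atrial transcripts, or summed counts of overlapping or near-identical gene models. Enrichment of Gene Ontology terms, as written in the deposited table, was tested among called genes with Fisher's exact test, one-sided, against tested genes carrying a term, for terms of 10 to 500 genes. Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.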

Results

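The study asked what MERTK, a receptor by which macrophages engulf dying cells, does in the pressure-overloaded heart, and its title ties this to the type I interferon response. Hearts were profiled by RNA sequencing 8 weeks after transverse aortic constriction in 4 wildtype libraries and 4 libraries labelled Mertk knockdown. The wildtype libraries held 59287621 to 71571173 counts and the labelled knockdown libraries 63378755 to 68762911. Mitochondrial transcripts took 29.81% ± 2.45 and 30.63% ± 1.16 of them (SD, n = 4 each).

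Mertk itself, the targeted gene (ENSMUSG00000014361, chromosome 2, 128698956 to 128802894, plus strand), was not lower in the libraries labelled Mertk knockdown. Its level was 11.05 ± 0.87 CPM in wildtype and 11.86 ± 0.951 CPM in the labelled group (SD, n = 4 each), and the values of the groups overlapped. The log2 fold change was 0.10 (SE 0.11, 95% interval −0.14 to 0.34, edgeR adjusted p = 0.766). An exact permutation test of log2 CPM, two-sided, gave p = 0.2571 for a difference of 0.10, and the deposited FPKM gave p = 0.3143. The count of the whole gene thus did not separate the groups as their labels would, and every direction below is that of the labels. The related receptors and their ligands did not pass either. Axl had a log2 fold change of −0.12, Tyro3 0.48, and the bridging ligands Gas6 and Pros1 −0.15 and −0.16. Of the 20 tested genes of the list of TAM receptors and efferocytosis, 0 were called over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.684, median log2 fold change −0.12).

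**Figure D1:**
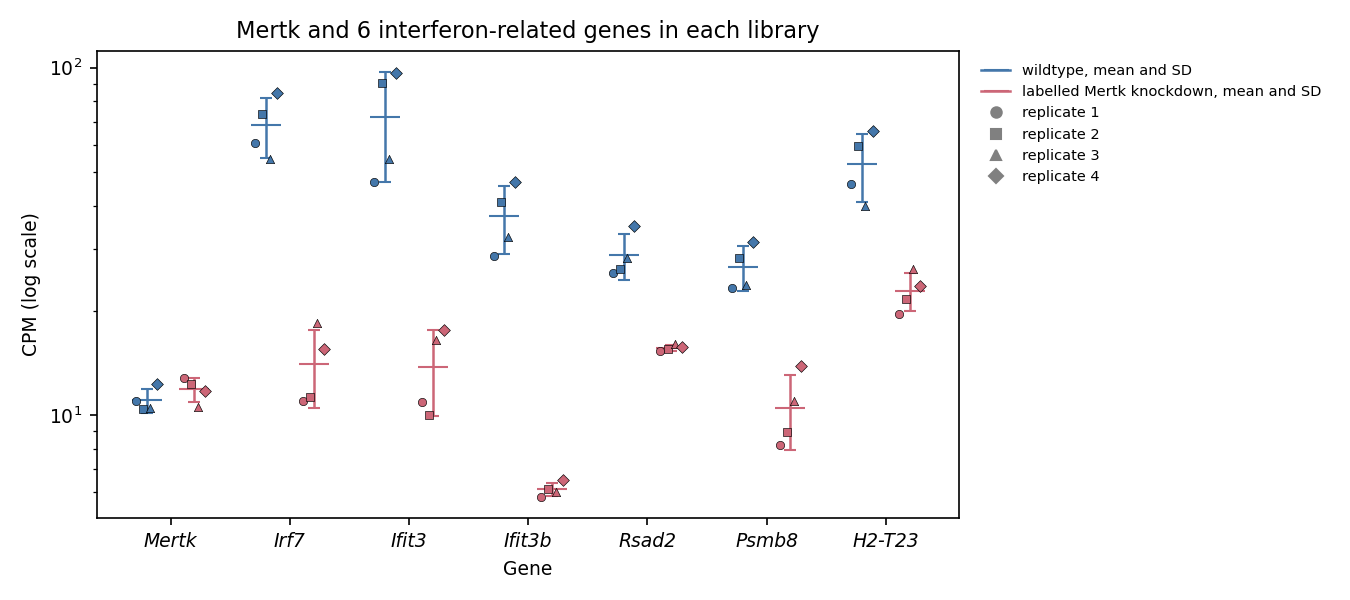
CPM (vertical log axis) of Mertk and 6 interferon-related genes in each library, with the mean and SD of the 4 wildtype (blue) and 4 labelled Mertk knockdown (red) libraries; marker shapes give the replicate number. Mertk values overlap between groups (means 11.05 and 11.86 CPM), while all 4 labelled knockdown libraries lie below all wildtype libraries for the other 6 genes. These 6 are called genes, none of which overlapped between the groups. Members of the type I interferon list that were not called, such as Stat2 and Parp14, did overlap.

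Among the fixed lists, the type I interferon-stimulated genes had the smallest camera adjusted p and were lower in the libraries labelled Mertk knockdown. Of the 40 tested type I interferon-stimulated genes, 12 fell over all genes by edgeR and 0 rose; 27 fell by DESeq2, and 2 with log2(FPKM + 1) and no filter. Adjusted over the list alone, 36 fell, and 39 had a log2 fold change below 0 (median −1.17). Ifit3b, an antiviral effector (chromosome 19, 34607970 to 34613401), was 6.10-fold lower, with 37.36 ± 8.25 CPM in wildtype and 6.13 ± 0.281 CPM in the labelled group (log2 fold change −2.61, SE 0.16, edgeR adjusted p = 0.0001318). Irf7, the transcription factor that amplifies type I interferon production (chromosome 7, 141262706 to 141266481), was 4.87-fold lower, at 68.3 ± 13.4 against 14.03 ± 3.56 CPM (log2 fold change −2.28, SE 0.20, edgeR adjusted p = 0.001251). Oas3 and Oasl1, of the oligoadenylate synthetase family that senses double-stranded RNA, fell by 2.68 and 2.17 on the log2 scale. The call of Oas3 was lost without labelled knockdown replicate 1, 3 or 4 (adjusted p of 0.05214 to 0.05647). Ifit3 fell by 2.39, Ifit2 by 1.32 and Rsad2, which encodes the antiviral enzyme viperin, by 0.88. Other called members were Usp18 (−1.81), which restrains interferon receptor signalling, Bst2 (−1.20), Ifi211 (−1.07) and Lgals3bp (−1.03). Ifit1 (−2.73, adjusted p = 0.0823) and Isg15 (−1.69, adjusted p = 0.111) did not pass over all genes in edgeR. Ifit3 and Ifit3b are near-identical copies whose reads may be shared; their summed counts had a log2 fold change of −2.46 (SE 0.23, adjusted p = 0.002359).

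The mean log2 CPM of the list was 4.23 ± 0.542 in wildtype and 3.00 ± 0.201 in the labelled group (SD, n = 4 each), a difference of −1.23 (exact permutation test, two-sided, p = 0.0286, the smallest this design can give; 0.181 after adjustment over 38 lists). All 4 labelled libraries lay below all 4 wildtype ones. With camera the list was lower than other genes (adjusted p = 2.344e-27), and this call was lost with the inter-gene correlation estimated (adjusted p = 0.382 with an estimated correlation). Hepatocyte marker transcripts marked the same libraries in part. They summed to 309 to 385 CPM in all 4 labelled libraries and to 363 CPM in wildtype replicate 1, but to 53.6 to 56.1 CPM in wildtype replicates 2 to 4. The 5 libraries with hepatocyte transcripts hold 1 wildtype and 4 labelled libraries, so in every fit to them the spread comes from the labelled group alone, and the lone wildtype library is assumed to vary like it. Among them, 2 members fell over all genes and 12 over the list alone (median −0.50). With the marker score as a covariate these numbers were 2 and 12 (median −0.40). Without atrial tissue markers (5 libraries) 1 fell over all genes and 30 over the list alone (median −1.21). Leaving out 1 library gave 17 fallen members without wildtype replicate 1, 7 without wildtype replicate 2, 10 without replicate 3 and 6 without replicate 4. It gave 5 without labelled knockdown replicate 1, 6 without replicate 2, 5 without replicate 3 and 7 without replicate 4.

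Genes induced by interferon-gamma and genes of MHC class I presentation were lower as well. All 22 tested interferon-gamma induced genes had a log2 fold change below 0 (median −1.84), 1 fell over all genes and 21 fell when adjusted over the list alone. The called gene was Psmb8, an immunoproteasome subunit (chromosome 17, 34197721 to 34201454), at 26.71 ± 4.01 CPM in wildtype and 10.5 ± 2.54 CPM in the labelled group (log2 fold change −1.35, SE 0.18, edgeR adjusted p = 0.01266). The GTPases Igtp (−3.49), Iigp1 (−3.48) and Irgm2 (−2.76) had larger fold changes, but the wildtype libraries varied widely and none passed over all genes (Iigp1, 516 ± 473 against 46.36 ± 21.6 CPM). Of the 10 genes of MHC class I presentation, 2 fell over all genes and all 10 over the list alone (median −0.79). H2-T23, a non-classical class I gene, had a log2 fold change of −1.21 (SE 0.16, edgeR adjusted p = 0.01294), and H2-Q4 of −0.81 (SE 0.14, edgeR adjusted p = 0.04196). The call of H2-Q4 was lost without wildtype replicate 2, 3 or 4 and without labelled knockdown replicate 1, 2 or 3 (adjusted p of 0.05715 to 0.118). B2m, the shared light chain, did not pass (−0.95, adjusted p = 0.0624). MHC genes are a family of similar copies, so single members are uncertain. Camera adjusted p was 1.135e-15 for the interferon-gamma list and 2.86e-10 for MHC class I; with an estimated correlation the adjusted p were 0.4726 and 0.2998. Within the 5 libraries with hepatocyte transcripts the medians were −0.77 and −0.97, 0 members of either list fell over all genes by edgeR, and 8 of each fell over the list alone. With the hepatocyte score as a covariate the medians were −0.64 and −0.95, again 0 fell over all genes, and 1 interferon-gamma gene and 8 MHC class I genes fell over the list alone. By DESeq2 on all libraries, 15 interferon-gamma induced genes and 9 MHC class I genes fell. Leaving out 1 library gave 1 fallen interferon-gamma gene, or 2 without wildtype replicate 1. It gave 3 fallen MHC class I genes without labelled knockdown replicate 4, 2 without wildtype replicate 1 and 1 without any of the others.

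Upstream of these genes, no single receptor or sensor of interferon was called. The list was lower by camera at its preset correlation (median −0.19, adjusted p = 0.04155) and not with an estimated correlation (adjusted p = 0.434) or by fry (adjusted p = 0.08735). Of 20 tested genes of interferon sensing and signalling, 0 were called over all genes (edgeR) and 1 fell over the list alone. That gene was Samhd1, a restriction factor that degrades deoxynucleotides, with a log2 fold change of −1.02 (SE 0.20, adjusted p = 0.0614 over all genes). Irf5 followed with −0.83 (adjusted p = 0.193). The endosomal sensors Tlr7 and Tlr9 had −0.70 (adjusted p = 0.279) and −0.75 (adjusted p = 0.511), and the feedback inhibitors Socs1 and Socs3 −1.07 and −0.62. The receptor subunits Ifnar1 and Ifnar2 had log2 fold changes of 0.16 and 0.01, and Cgas and Sting1, of the cytosolic DNA sensing pathway, 0.27 and 0.16; none of these 8 passed. The camera call of the list was also lost without wildtype replicate 1 (camera adjusted p = 0.05044) or 2 (0.09255), without labelled knockdown replicate 1 (0.07289) or 4 (0.05498), and within the 5 libraries with hepatocyte transcripts (0.1612).

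**Figure D2:**
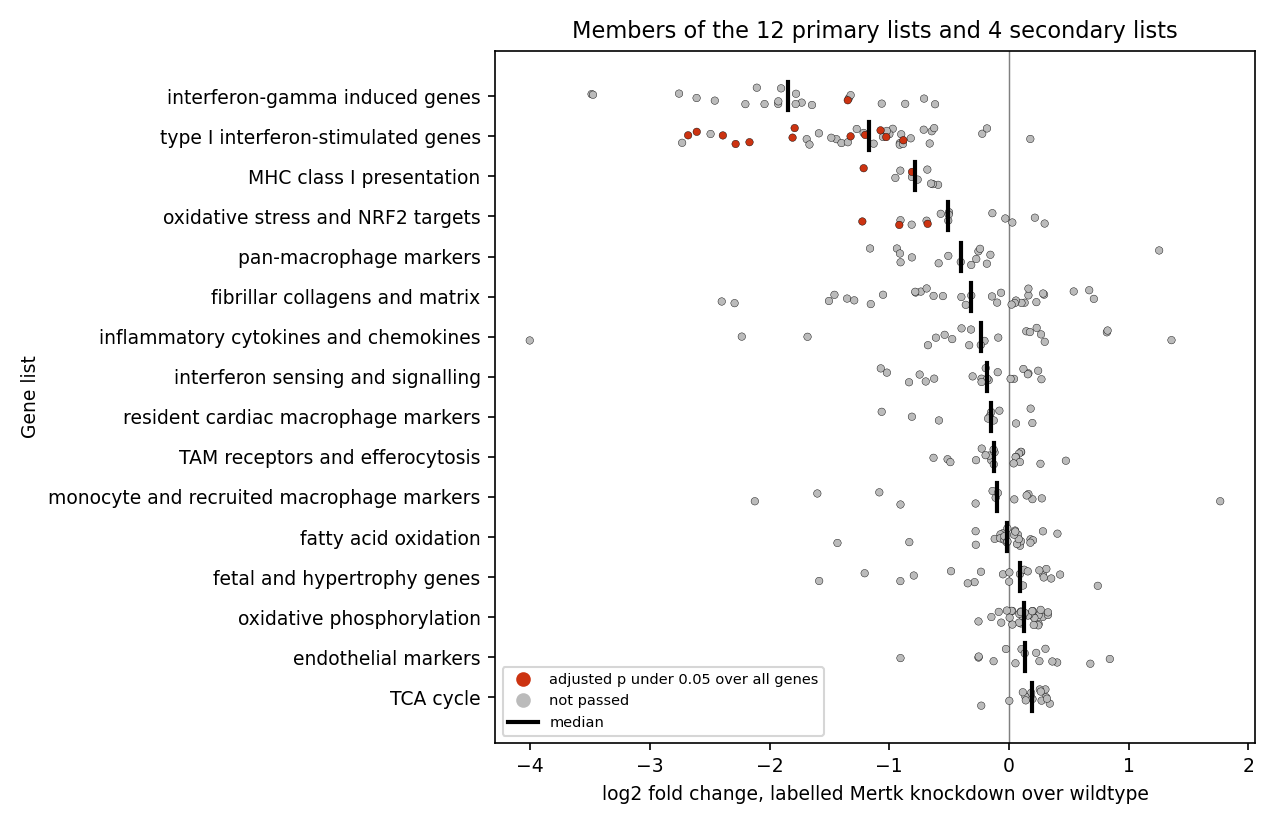
Log2 fold change (horizontal axis, labelled Mertk knockdown over wildtype) of each tested member of the 12 primary and 4 secondary gene lists (rows, ordered by median); red points have an edgeR adjusted p under 0.05 over all genes, grey points do not, and black bars are medians. Among the lists shown, the interferon-gamma list (median −1.84) and the type I interferon list (median −1.17) lie farthest from 0, and the fatty acid oxidation list lies at −0.01. The adipose list (median −1.72) is not shown.

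No single gene of the macrophage marker lists was called over all genes, and the list of pan-macrophage markers was lower by camera at its preset correlation (adjusted p = 0.0002458). With an estimated correlation its adjusted p was 0.726, by fry 0.2825, and within the 5 libraries with hepatocyte transcripts 0.6128 by camera. Of the 15 pan-macrophage markers, 0 passed over all genes (edgeR), 4 fell over the list alone and 14 had a log2 fold change below 0 (median −0.40). The lysosomal protease Ctss had −0.91 (adjusted p = 0.165) and Laptm5 −0.40 (adjusted p = 0.166). The score difference was −0.43 (exact permutation test, two-sided, p = 0.2). Markers of resident cardiac macrophages (11 tested) had 0 called over all genes or over the list alone, with Cd163 at −0.81 (adjusted p = 0.236) and Vsig4 at −1.06 (adjusted p = 0.508). Among the markers of monocytes and recruited macrophages (14 tested) 0 were called over all genes and 1 over the list alone, Ms4a4c at −2.12 (adjusted p = 0.0754); Ly6c2 had −0.91 (adjusted p = 0.212). The list of inflammatory cytokines and chemokines (21 tested) had 0 called over all genes and 2 lower over the list alone. Ccl8 had −2.23 (adjusted p = 0.0504) and Nfkbia, the inhibitor of NF-kappa-B, −0.68 (adjusted p = 0.134). Camera adjusted p were 0.375, 0.372 and 0.212 for these last 3 lists. Of the neutrophil markers (8 tested), Lcn2, an iron-sequestering lipocalin, fell (log2 fold change −1.28, SE 0.21, edgeR adjusted p = 0.03298; list camera adjusted p = 0.005133, and adjusted p = 0.304 with an estimated correlation). The call of Lcn2 was lost without wildtype replicate 3 or 4 or without any 1 labelled library (adjusted p of 0.05688 to 0.1048). Within the 5 libraries with hepatocyte transcripts the neutrophil list gave a camera adjusted p of 0.1787. Most of that list's members were below 2 CPM on average. The C1q subunits C1qb and C1qc, which tag dying cells, had −0.63 and −0.51 and did not pass.

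The usual readouts of hypertrophy and fibrosis did not pass the test. Of the 23 fetal and hypertrophy genes 0 were called over all genes by edgeR, and 2 were higher and 1 lower over the list alone. Ankrd1, a stretch-responsive nuclear protein, had −0.91 (SE 0.20, adjusted p = 0.0845). Myh6, the adult heavy chain of cardiac myosin, had 0.74 (SE 0.20, adjusted p = 0.160), and the calcium pump gene Atp2a2 0.43 (adjusted p = 0.185). Myh7, the fetal heavy chain, was at 8115 ± 3052 CPM in wildtype and 2704 ± 2333 CPM in the labelled group (log2 fold change −1.59, SE 0.58, edgeR adjusted p = 0.327). The natriuretic peptide genes Nppa and Nppb had log2 fold changes of −0.80 (SE 0.83) and 0.00 (SE 0.48). The median of this list was 0.09, its mean −0.11, and camera gave an adjusted p of 0.941. Of 33 collagen and matrix genes, 0 passed over all genes or over the list alone (edgeR). Col1a1 had 0.06 (SE 0.68), Col3a1 0.05 (SE 0.89) and Postn, a matrix protein of activated fibroblasts, −1.46 (SE 1.13). The libraries varied widely for these 3 genes (Col3a1, 166.4 ± 167.8 and 172.1 ± 112.9 CPM), so that a difference of several fold was not detectable here. Camera gave an adjusted p of 0.941 for the collagen list (median −0.31). The list was called upward without wildtype replicate 2 (camera adjusted p = 0.0166), with the hepatocyte covariate (0.001473) and within the 5 libraries with hepatocyte transcripts (2.377e-05). The list of TGF-beta signalling (18 tested) gave a camera adjusted p of 0.130.

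No gene of the lists of mitochondrial metabolism (oxidative phosphorylation, TCA cycle and fatty acid oxidation) was called over all genes by edgeR. The oxidative phosphorylation and TCA cycle lists were higher by camera at its preset correlation (adjusted p = 0.005133 and 0.0008349) and not with an estimated correlation (adjusted p = 0.758 for each) or by fry (0.502 and 0.2825). Of 30 oxidative phosphorylation genes, 25 had a log2 fold change above 0 (median 0.12), among them Cyc1 at 0.28. Of 15 genes of the TCA cycle, 14 were above 0 (median 0.20). In both lists 0 genes passed over all genes (edgeR) or over the list alone. The first camera call was also lost without wildtype replicate 1 (camera adjusted p = 0.0835) or 2 (0.1117), and the second within the 5 libraries with hepatocyte transcripts (0.1131). Fatty acid oxidation genes (27 tested, 0 called by edgeR, median −0.01) gave a camera adjusted p of 0.983, with Pdk4 at −0.83 (adjusted p = 0.169) and Cpt1a at −0.28 (adjusted p = 0.306). This list was called downward without wildtype replicate 2 (camera adjusted p = 0.01991), with the hepatocyte covariate (0.01365) and within the 5 libraries with hepatocyte transcripts (0.003398). The sign of its main camera test was up while its median and mean (−0.06) were below 0. In the list of oxidative stress and NRF2 targets, 3 of 15 genes fell over all genes, and 8 fell and 1 rose over the list alone. The 3 genes were the metallothioneins Mt1 (−0.92, edgeR adjusted p = 0.0138) and Mt2 (−1.23, edgeR adjusted p = 0.04896), which bind metal ions, and Gclm (−0.68, edgeR adjusted p = 0.02555), a subunit of the first enzyme of glutathione synthesis. Mt2 kept its call in 6 of 23 alternative settings, and lost it without wildtype replicate 3 or 4 or any 1 labelled library (adjusted p of 0.0942 to 0.1537). Mt1 lost it without labelled knockdown replicate 3 (0.05845), and Gclm without wildtype replicate 4 or any 1 labelled library (0.06824 to 0.08342). The list gave a camera adjusted p of 0.0002458 (adjusted p = 0.163 with an estimated correlation).

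Over all genes, 115 of 17787 were called by edgeR, 49 higher and 66 lower in the libraries labelled Mertk knockdown. The values of the groups did not overlap for any of the 115. Among all tested genes 1436 (8.1%) did not overlap, where chance gives 2.86% on average over splits of the libraries. Genes vary together, so 1 split can lie far from that average, and the share in other splits was not computed. At an unadjusted p under 0.05 there were 1087 higher and 1124 lower genes. Among called genes with a mean of at least 1 CPM and no predicted or clone name, the higher ones were led by mt-Tg, a mitochondrial tRNA gene of low count (log2 fold change 3.96, SE 0.54, edgeR adjusted p = 0.01806), and by Ifi208 (3.51, SE 0.47), a member of the interferon-inducible p200 family on chromosome 1 at 173673675 to 173698395. Apelin and its receptor both rose, with calls that depended on single libraries. Aplnr (chromosome 2, 85136225 to 85139923) went from 6.37 ± 1.74 to 32.88 ± 17 CPM (log2 fold change 2.37, SE 0.36, edgeR adjusted p = 0.03546), and Apln, its peptide ligand (chromosome X, 48025146 to 48034853), from 3.06 ± 1.46 to 13.1 ± 3.29 CPM (4.27-fold, edgeR adjusted p = 0.03225). Aplnr kept its call in 11 and Apln in 15 of 23 alternative settings, each with a log2 fold change of at least 1.36 in all of them. Aplnr lost it without any 1 wildtype library or labelled knockdown replicate 4 (adjusted p of 0.05488 to 0.1053), and Apln without wildtype replicate 2 or 3 or any 1 labelled library (0.06191 to 0.08952). The other higher genes by the fixed rule were Lingo3 (4.26-fold), Tmem267 (4.19-fold), Plac9a (3.74-fold), Erdr1 (3.28-fold), Lrrc4b (3.19-fold) and Bcl6b (2.86-fold), a transcriptional repressor. Plac9a and Erdr1 lie in repeated sequence and their counts are uncertain. Jun, an immediate early transcription factor, rose from 62.15 ± 7.87 to 107.2 ± 21.4 CPM (0.79, SE 0.15, edgeR adjusted p = 0.04712), a call kept in 7 of 23 alternative settings and lost on leaving out any 1 library (adjusted p of 0.0519 to 0.1205). Of the other genes named here, Ifi208 kept its call in all 8 fits with 1 library left out, Lingo3 in 7, Tmem267 in 6, mt-Tg in 4, Bcl6b, Erdr1 and Lrrc4b in 3 and Plac9a in 2, with adjusted p of at most 0.1276.

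Besides the interferon-stimulated genes, the lower genes included Clca3a1 (5.40-fold lower), the lipocalin Apod (4.09-fold lower, edgeR adjusted p = 0.002361), the Fc receptor Fcgr4 (4.06-fold lower), the glutamate transporter Slc1a2 (3.74-fold lower) and the complement gene C4b (3.59-fold lower). Apod was at 32.45 ± 6.38 CPM in wildtype and 7.94 ± 1.91 CPM in the labelled group, and C4b at 89.32 ± 20.1 and 24.86 ± 9.01 CPM. C4b has a close copy, C4a, with which reads may be shared. Apod and Fcgr4 kept their calls in all 8 fits with 1 library left out. C4b kept its call in 5 of them, Clca3a1 in 3 and Slc1a2 in 1 (adjusted p of at most 0.1386). Genes within 10 Mb of Mertk were not called more often than others (1 of 224, Inafm2, against 114 of 17562 elsewhere; Fisher's exact test, two-sided, p = 1).

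These counts changed with the libraries used. Without wildtype replicate 1 there were 165 higher and 100 lower genes. Without wildtype replicate 3 there were 21 and 42, and without wildtype replicate 4 there were 18 and 30. Without labelled knockdown replicates 1, 2, 3 and 4 there were 20 and 30, 18 and 38, 15 and 29, and 19 and 42. Within the 5 libraries with hepatocyte transcripts 19 were higher and 23 lower, of which 5 and 10 were among the 115. Atrial myocyte markers (Myl7, Myl4, Sln) summed to 329, 195 and 618 CPM in wildtype replicates 3 and 4 and labelled knockdown replicate 4 and to at most 3.98 CPM elsewhere; the 5 libraries without them (2 wildtype and 3 labelled) gave 2 higher and 4 lower genes. Both subsets hold fewer libraries, and the effect of the admixed transcripts was not separated from that. DESeq2 called 255 higher and 328 lower.

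**Figure D3:**
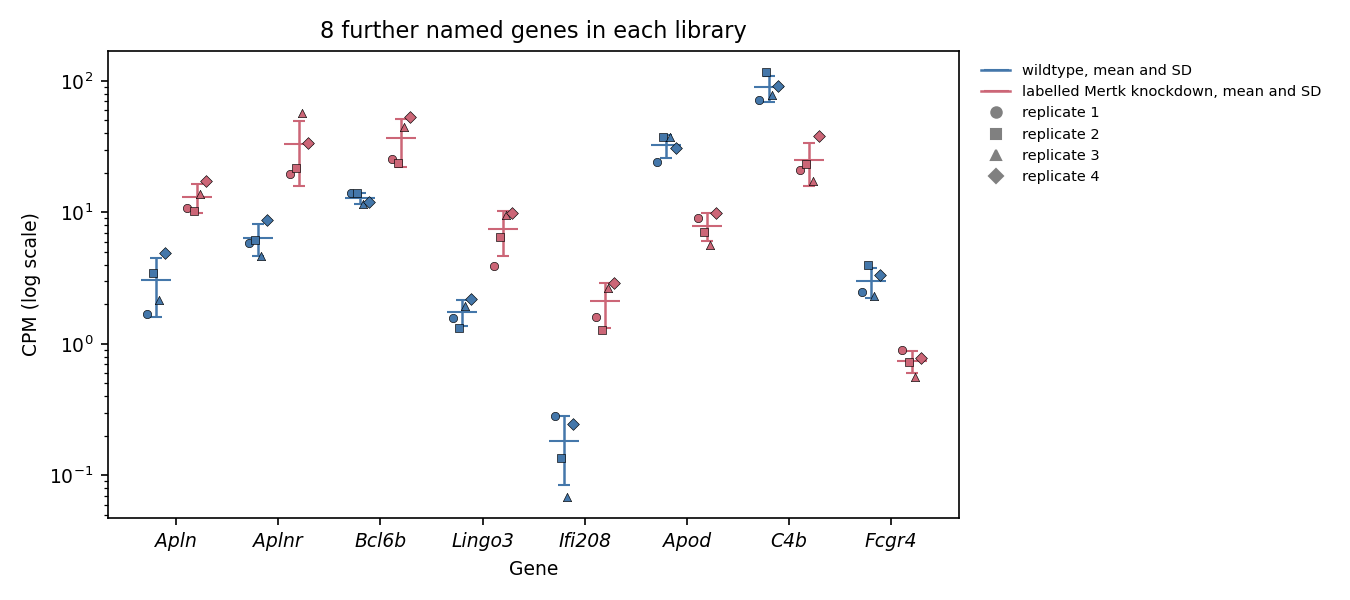
CPM (vertical log axis) of 8 further named genes in each library, with mean and SD of the 4 wildtype (blue) and 4 labelled Mertk knockdown (red) libraries; marker shapes give the replicate number. Apln, Aplnr, Bcl6b, Lingo3 and Ifi208 are higher in all 4 labelled libraries and Apod, C4b and Fcgr4 lower; Aplnr went from a mean of 6.37 to 32.88 CPM.

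**Figure D4:**
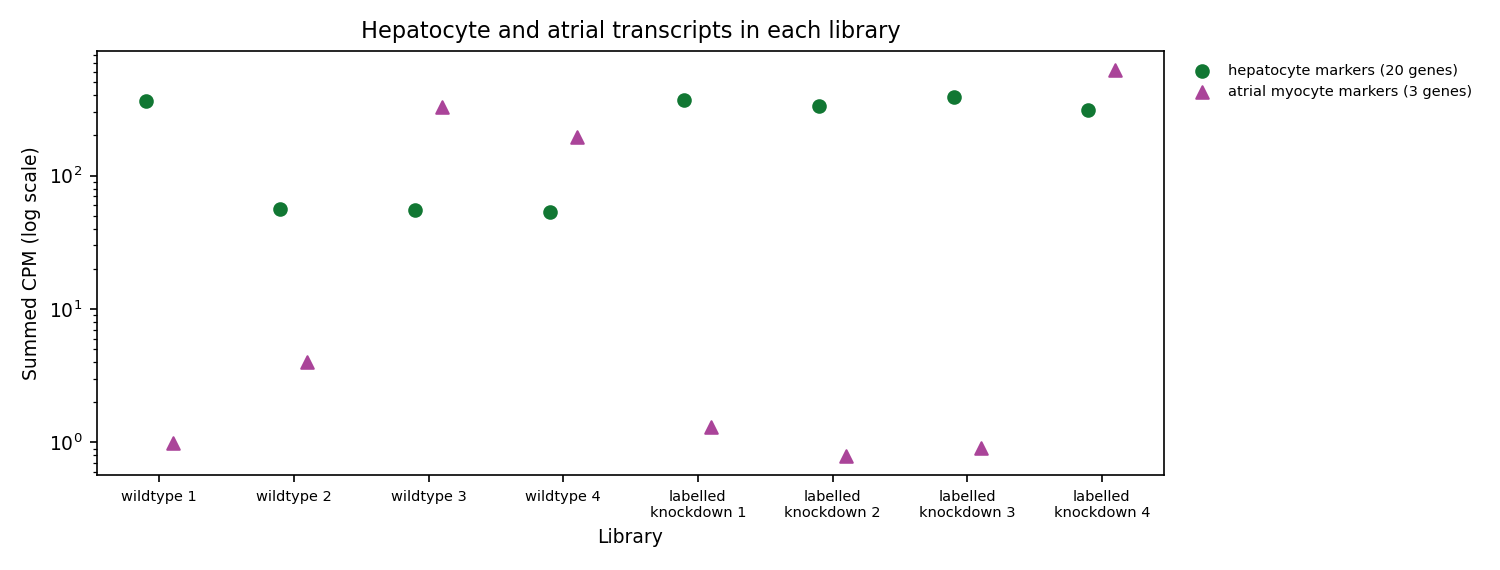
Summed CPM (vertical log axis) of 20 hepatocyte markers (green circles) and 3 atrial myocyte markers (purple triangles) in each of the 8 libraries. Hepatocyte markers lie at 309 CPM or more in wildtype replicate 1 and all labelled knockdown libraries and at 53.6 to 56.1 CPM in the other 3; atrial markers exceed 190 CPM in 3 libraries.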

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

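The comparison of libraries by hepatocyte transcripts and the test for swapped libraries were chosen after the results were seen; the other tests of this part were planned.

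The lower interferon-stimulated genes in the libraries labelled Mertk knockdown invite a closer look because a technical marker runs almost along the groups. Chance as the account of the number of called genes is argued against by the 35 splits of the 8 libraries. Only 1 of them, the real one, gave as many higher (49) or lower (66) genes, and the highest other split gave 12. First of 35 is the most these splits can show, and a batch running almost along the groups could rank first too. Chance stays open for the number of gene lists, as 15 of 35 splits gave at least 11 lists and the highest other 19. Fewer macrophages as the whole account is argued against by the interferon score minus the pan-macrophage score per library, which was 0.92 ± 0.122 in wildtype and 0.11 ± 0.12 in the labelled group (n = 4 each, exact permutation test, two-sided, p = 0.02857, the smallest possible). A library batch stays open: 19 of 20 hepatocyte markers were higher in each of 5 libraries (wildtype replicate 1 and the 4 labelled ones) than in each of the other 3, led by albumin (Alb, mean 99.5 against 1.94 CPM, and 49.67 to 125.7 CPM within the 5). They may come from carry-over between libraries handled together. Of the 20 genes, 4 reached 1 CPM on average in the other 3 libraries as well, and 0 are in another list. The axis of largest spread in log2 CPM over all tested genes (first principal component, 32.1% of the variance) divided the libraries as these markers did. Wildtype replicate 1 lay at −23.9 and the labelled libraries at −40.65 to −27.78, against 42.37 to 70.35 for wildtype replicates 2 to 4. The genes behind this axis included hepatocyte markers and it was not recomputed without them, so it is no separate evidence of a batch. Wildtype replicate 1, the single wildtype library of that kind, had an interferon score of 3.67. That lies 0.668 above the labelled mean and above their highest (3.22). It is below wildtype replicate 3 (3.87), and farther below replicates 2 and 4 (4.68 and 4.72). In the interferon-gamma score, replicate 1 (4.52) was above replicate 3 (4.41) and below replicates 2 and 4 (6.15 and 6.29). In the MHC class I score it was the highest wildtype library (6.77, others 6.64 to 6.66). Batch and group cannot be told apart with 1 such library.

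The level of Mertk in the libraries labelled Mertk knockdown is the other result to examine, since it was not lower than in wildtype (exact permutation test, p = 0.2571). Mertk lay at 10.395 to 12.289 CPM in the wildtype libraries and at 10.577 to 12.788 CPM in the labelled ones. No exchange among these 8 libraries would therefore give a group with Mertk far below the other. By called genes, an exchange would need a library out of place on each side. Each labelled library lay nearer its own group in at least 84.1% of the genes called without it. Wildtype replicate 1 was the single library that lay nearer the other group in most (42.4% nearer its own). This also argues against an exchange. What stays open, untested here, is a knockdown confined to a cell type that gives little of the heart's Mertk, or an altered transcript that still yields reads over the gene. Group labels that differ from the mice, other than by an exchange among these libraries, stay open too.

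Single libraries lay far from the other 3 of their group in 8 of 132 sets of 4 values, where chance alone gives about 6.6. Hepatocyte marker transcripts reached 362.7 CPM in wildtype replicate 1, against 53.57 to 56.12 CPM in the other wildtype libraries. Atrial myocyte markers reached 618.0 CPM in labelled knockdown replicate 4, against 0.796 to 1.294 CPM in the rest of its group. Wildtype replicate 2 had 293.0 CPM of Nppb (others 66.23 to 93.06) and 3.41 CPM of Lrrc4b (others 6.518 to 7.002). Wildtype replicate 3 had 68.84 CPM of H2-Q4 (others 81.89 to 83.93), and wildtype replicate 4 had 3.598 CPM of Ccl8 (others 2.019 to 2.218). Labelled knockdown replicate 2 had 15.87 CPM of Pros1 (others 18.73 to 18.93) and a mitochondrial share of 28.9% (others 31.05% to 31.35%).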

How the results depend on the processing

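The use of hepatocyte and atrial scores, of the libraries chosen by them, and of summed copies was decided after seeing the data. The direction of all 115 called genes was kept wherever they were tested, and the number of calls was not. With RLE or upper quartile factors, no filter, a mean of at least 1 CPM, limma-voom or summed copies, the counts stayed within 1.5 times of 49 higher and 66 lower genes. Higher and lower counts were 255 and 328 with DESeq2, 28 and 43 with log2(FPKM + 1), 27 and 42 with log2(FPKM + 0.1), and 8 and 13 with log2(FPKM + 1) without a filter. They were 26 and 39 at a log2 fold change of at least 1, and 102 and 130 at an adjusted p under 0.1. Leaving out 1 library gave 15 to 165 higher and 29 to 100 lower genes, both lowest without labelled knockdown replicate 3 and highest without wildtype replicate 1. The 5 libraries with hepatocyte transcripts gave 19 and 23, the hepatocyte covariate 6 and 11, the atrial covariate 16 and 41, and the 5 libraries without atrial transcripts 2 and 4; these fits have fewer libraries or one more term. The cause of the other shifts was not tested.

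Replicate numbers did not pair the samples: correlations of same-numbered deviations were 0.062, 0, −0.006 and 0.181, and 1 of 4 numbers correlated best with its own. A replicate block gave 5 higher and 19 lower genes, and 5 lower type I interferon genes. Of the 30 named genes called, it kept 8, and 264 of 683 alternative values over all settings lost the call with 0 reversed. Leaving out 1 wildtype library kept 28, 23, 19 and 14 of the 30 (replicates 1 to 4) and leaving out 1 labelled library 16, 16, 13 and 17. Ifit3b kept its call in all 22 settings that tested it and Irf7 in 22 of 23. Of the 31 other named genes, 23 of 707 values gained a call; Mertk gained none.

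For the lists, 11 of 37 were called by camera, 0 with an estimated correlation and 4 by fry, which tests each list by itself. The type I interferon list had an adjusted p of 0.382 with an estimated correlation and kept its call under the other camera settings. The collagen list turned upward within the 5 hepatocyte libraries (1 wildtype, assumed to vary like the 4 labelled; adjusted p = 2.377e-05), with the hepatocyte covariate (0.001473) and without wildtype replicate 2 (0.0166; range 0.0166 to 0.843 over left-out libraries). The fatty acid oxidation list turned downward in the same settings (0.003398, 0.01365 and 0.01991; range 0.01991 to 0.9851), and the adipose list turned upward within the 5 libraries (0.8229). The cause was not tested. Depth limits little here, at 59287621 counts or more per library; the spread between libraries limits the matrix genes.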

Other observations

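The tests on genetic background and on gene copies were chosen after the values were seen; the test around Mertk was planned.

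Among Gene Ontology terms in the deposited table, 11 of 3645 were enriched in the lower genes (Fisher's exact test, one-sided, adjusted p under 0.05) and 0 in the higher genes. At an unadjusted p under 0.05 there were 112 and 83 terms. The leading terms of the lower genes were response to virus (8 of 76 genes, adjusted p = 4.942e-06), defense response to virus (9 of 148, adjusted p = 2.909e-05) and cellular response to interferon-beta (5 of 44, adjusted p = 0.001644). Binding of beta-2-microglobulin (H2-Q4, H2-T23 and Hfe, adjusted p = 0.007995) and tissue regeneration (Apod, Cdkn1a and Ninj1, adjusted p = 0.03406) followed. The top term of the higher genes was coronary vasculature development (Apln, Aplnr and Plxnd1), with an adjusted p of 0.3004.

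Vascular and contractile lists had no gene called over all genes by edgeR. Values in parentheses after a list are camera adjusted p, and those after a gene are log2 fold changes. Of 15 endothelial markers, 4 were higher when adjusted over the list alone, Kdr (0.68), Cldn5 (0.84), Cdh5 (0.40) and Emcn (0.36), and Rgcc (−0.91) was lower; the list's camera adjusted p was 0.0840. Smooth muscle and pericyte markers (camera adjusted p = 0.375), sarcomere genes (0.415), fibroblast markers (0.375), epicardial markers (0.433) and skeletal muscle markers (0.191) were not called. Of the sarcomere genes Tcap (−0.77) was lower over the list alone. Among lymphoid and myeloid lists, T and NK cell markers (0.595), B and plasma cell markers (0.154) and mast cell markers (0.983) were not called, while dendritic cell and MHC class II genes were (median −0.29, camera adjusted p = 0.04902; adjusted p = 0.758 with an estimated correlation). The latter call was lost on leaving out any 1 library but wildtype replicate 2 and labelled knockdown replicate 4 (adjusted p of 0.06471 to 0.2058 in those 6 fits). Of 19 immediate early genes Jun rose, a call lost on leaving out any 1 library (adjusted p of 0.0519 to 0.1205); Egr3 (1.38) was higher over the list alone and Egr1 (1.99, adjusted p = 0.291) did not pass (camera adjusted p = 0.375). Lists for glycolysis (0.131), mitochondrially encoded genes (0.433), the unfolded protein response (0.375), cell cycle (0.415), circadian clock (0.637), heat shock (0.212), erythroid genes (0.105) and atrial and valve tissue (0.0840) were not called. The circadian list had a median of 0.01 and a mean of 0.04 with a camera test downward, and the cell cycle list a median of 0.11 and a mean just below 0 with a test upward. Over the list alone, Hk2 (0.39) of the glycolysis list and Kit (0.89) of the mast cell list were higher, and Clu (−0.58) of the atrial and valve list was lower. Adipose markers were lower by camera (median −1.72, adjusted p = 0.04637; adjusted p = 0.758 with an estimated correlation), a call lost without wildtype replicate 3 (0.3229) or 4 (0.06471) or without labelled knockdown replicates 2 to 4 (0.0566, 0.09885 and 0.06847). The 2 thymus and lung markers were too few to test.

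Outside the interferon and MHC lists, 47 called genes with a mean of at least 1 CPM had a clear gap between the groups: the lowest library of the higher group was at least 1.5 times the highest library of the lower group. Wdfy1, a protein of Toll-like receptor signalling, was at 24.87 ± 3.07 CPM in wildtype with a log2 fold change of −1.75 (edgeR adjusted p = 0.0001318), and Rab4a (−1.62), Hand2 (−0.90), Dynlt1b (−1.44) and Tmem181b-ps (−1.62) were also lower; Entpd4 (1.21) and Entpd4b (1.07) were higher. In the p200 cluster on chromosome 1, Ifi208 was higher while Ifi205 (−1.40) and Ifi207 (−1.06) were lower. A hypothesis is that the groups differ in genetic background or copy number, as several of these genes have near-identical neighbours. The 47 genes shared 3 loci within 1 Mb (Dynlt1b with Tmem181b-ps, Plac9a with Gm9780, and the Entpd4 region), where random sets of matched expression had a median of 1 and at least as many in a share of 0.1974, so the test leaves this open. In the Entpd4 region, Gm16867 overlaps Entpd4 and Gm27177 overlaps Entpd4b on the opposite strand, so this locus may rest on shared reads. Reads moved between Entpd4 and Entpd4b alone are argued against, as both were higher. Their summed counts had a log2 fold change of 1.141 (SE 0.086, edgeR adjusted p = 0.0003209), which follows from this and is no separate test. The sum left out Gm16867 and Gm27177. For the lower genes the sums were called but nearer 0: −0.797 for 4 Dynlt1 copies (SE 0.117, adjusted p = 0.01807) and −0.811 for Tmem181a with Tmem181b-ps (SE 0.082, adjusted p = 0.002485). This argues against moved reads as the whole account. For Ifi208 it stays open, since the sum with Ifi205 and Ifi207 was lower (−1.099, SE 0.116, adjusted p = 0.003263). Flanking sequence of a Mertk allele reaching up to 10 Mb is argued against for the 47 genes, as none of them lies within 10 Mb of Mertk. Bcl2l1, Slc1a2 and Aplnr lie farther off on chromosome 2, and a flank reaching them was not tested. For called genes as a whole, Fisher's exact test (p of 1) cannot decide. Calls were rare everywhere, at 1 of 224 genes within 10 Mb and 0.649% elsewhere. The labels do not say how Mertk was lowered.

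Nnt, a mitochondrial transhydrogenase that carries a deletion in the C57BL/6J strain, appears as 2 overlapping gene models. The second model took 96.0% of the Nnt counts in wildtype replicate 1, 0 in wildtype replicates 2 to 4, and 32.2% to 90.8% in the labelled libraries. Its presence thus divided the libraries as the hepatocyte markers did. Both models summed to 937 ± 324 CPM in wildtype and 482.5 ± 76.3 CPM in the labelled group (log2 fold change −0.96, edgeR adjusted p = 0.1403).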
